A study of Homo sapiens with 6 samples.

How the data were processed

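RNA was sequenced from KBM7 cells, a near-haploid human line derived from chronic myelogenous leukemia, after 6 h with the solvent DMSO or with W7, a withanolide analogue known here only by its code name, at 4 times its EC50. Each group held 3 libraries, and all 6 were used. Cells grew in IMDM with fetal bovine serum and antibiotics, and libraries were made with a Lexogen CORALL total RNA kit after poly-A enrichment, per the labels' protocols. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

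The deposited values are whole-number read counts per gene, with no normalization by the authors. Trimmomatic 0.32, STAR 2.5.2b, Picard and HTSeq 0.11.2 and the build GRCh38.p7 (hg38) are named in the submitters' processing notes, without the order or settings of the steps. The strand setting of the counting, the use of molecular identifiers, the handling of duplicates and the annotation release are not given in the sources used here. Without a stated strand setting, reads of a gene and of a gene on the opposite strand that shares its exons cannot be told apart. Each table listed the same 58051 genes, each as an Ensembl identifier joined to a symbol, and 28964 of them had at least 1 count. The tables held no lines for unassigned reads. Coordinates, transcript length, GC content and exon overlaps came from GENCODE 44 on the same build, in which 56948 of the identifiers (98.1%) were found. Overlaps were computed with bedtools 2.31.1. Symbols are those of the deposited tables, so CERT1 appears as COL4A3BP.

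Library totals ran from 9354168 to 12107735 counts. Counts without molecular identifiers are not independent molecules, so counting error alone understates the error, and the tests below rest on the spread between libraries. Genes were kept by edgeR's filterByExpr with the groups, which left 13001. Counts were scaled by TMM factors and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, without a replicate term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. A standard error is the absolute log2 fold change divided by the square root of F. CPM, the counts of a gene scaled to a fixed library total, were computed here from the deposited counts with the TMM factors, and log2 CPM used a prior count of 2.

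Before the data were examined, 30 gene lists (511 genes) were fixed from general knowledge of sterol and lipid metabolism, stress responses, the cell cycle, leukemic signalling and blood cell types, as were the main test, the other settings named below and the rule for named genes. The 27 lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The rule named OSBP first. It then took the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the groups. From each list that passed, and from the lists on cholesterol synthesis, sterol uptake, LXR targets and the OSBP family whether or not they passed, it took up to 4 members with the smallest adjusted p. From every other list it took at most 1 member, with an adjusted p under 0.05. Together this gave 59 genes, a few of which are not reported here. Other genes named in the text were chosen after their values were seen, and are said to be so where they appear.

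The other settings were RLE and upper-quartile scaling, no low-count filter, a filter of 1 CPM in at least 3 libraries, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, edgeR's glmTreat against a 1.5-fold change, and a prior count of 0.5. After the data had been examined, 3 more were added. All libraries were thinned at random to the smallest total. Per-library loess trends of log2 CPM on transcript length and on GC content (span 0.3) were removed through offsets in a single pass. Because the single pass left a trend with length, the trends were also fitted by turns in 5 rounds, and both versions are reported. This made 17 alternative gene counts. Single measures of the libraries were compared with exact two-sided permutation tests, which cannot give a p below 0.1 with 3 libraries against 3.

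The gene and list tests were tested on simulated data. Counts were drawn for 13001 genes from the means and totals of these libraries, and 200 of these genes were changed. The low-count filter then left 12890 genes, and the shares of changed genes found are among these. In this simulation of W7 against DMSO, 70.4% of genes changed 1.5-fold and 87% of genes changed 2-fold were found with the right sign, and 4.88% of the calls were unchanged genes. A list shifted as a whole was found with a median log2 of −0.49, and 0 unshifted lists passed. Counts were drawn independently for each gene, without length or GC trends. The simulation therefore cannot tell how often lists of correlated genes pass by error.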

Results

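Gene expression was measured by RNA sequencing in KBM7 cells, a leukemia line that grows in suspension, after 6 h with DMSO (3 libraries) or W7 (3 libraries). The DMSO libraries held 11723526, 11013664 and 11511121 counts and the W7 libraries 12107735, 11508188 and 9354168, with 21151 to 21420 genes detected in each. The series title places W7 among compounds that inhibit the oxysterol-binding protein OSBP, a carrier of cholesterol between the endoplasmic reticulum and the Golgi. The comparison therefore asks how the transcriptome, and sterol genes in particular, differed after short exposure to W7.

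In W7-treated cells, 11 of 20 tested cholesterol synthesis genes fell, as did 5 of 14 genes of sterol uptake and SREBP2 feedback and 5 of 13 of fatty acid synthesis, while 5 of 17 immediate early genes rose and 1 fell. These 4 lists passed camera with its preset correlation and none with an estimated one (adjusted p = 0.0627, 0.208, 0.251 and 0.208). INSIG1, which holds the sterol sensor SCAP in the endoplasmic reticulum, fell from 202.6 ± 1.89 to 83.7 ± 2.05 CPM (SD, n = 3 per group). Among genes with a mean of at least 10 CPM in the higher group, the largest rises were of HDAC9, a class IIa histone deacetylase, INHBA, which encodes a subunit of activin, and SUCNR1, the succinate receptor. OSBP itself stood at 122.3 ± 4.99 CPM with DMSO and 127.5 ± 9.34 CPM with W7 (SD, n = 3 per group), a log2 fold change of 0.06 ± 0.074 (SE) that did not pass (edgeR adjusted p = 0.712).

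In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 282 of 13001 genes passed (2.17%), 178 higher and 104 lower with W7. Of these, 41 rose and 7 fell by at least 1 on the log2 scale, and the smallest change that passed was 0.265. At an unadjusted p under 0.05 there were 2221 genes, and 1385 (without DMSO replicate 1) to 3062 (without W7 replicate 3) with 1 library left out. The libraries of both groups did not overlap for 24.7% of genes, where chance gives 10%. The number that passed depended on single libraries: 114, 112 and 116 genes without DMSO replicate 1, 2 or 3, 130 without W7 replicate 1, 268 without W7 replicate 2, and 1217 (680 higher, 537 lower) without W7 replicate 3, among which were all 282. A fit that tests for more than a 1.5-fold change passed 29 genes, 27 higher and 2 lower.

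HDAC9 (chromosome 7, 18086949 to 19002416) rose from 1.603 ± 0.496 to 12.19 ± 1.69 CPM (SD, n = 3 per group), 7.56-fold. INHBA (chromosome 7, 41667168 to 41705834) rose 6.32-fold, with a log2 fold change of 2.66 ± 0.141 (SE). SUCNR1 (chromosome 3, 151873643 to 151884619) rose from 20.81 ± 2.3 to 101.5 ± 1.12 CPM (SD, n = 3 per group), 4.88-fold, with the smallest adjusted p of all genes tested (2.84e-07, edgeR). The homeobox genes HLX and HOPX rose 4.71-fold and 4.58-fold. IL2RA, the alpha chain of the interleukin-2 receptor, rose 3.25-fold to 122.6 ± 2.99 CPM (SD, n = 3), and the membrane protein gene EMP1 rose 3.19-fold. TSLP, a cytokine gene, rose 2.98-fold to 15.35 ± 2.13 CPM (SD, n = 3). The log2 fold changes of the named falls ran from −1.28 for INSIG1 to −0.76 for SCD, and 6 of the 8 belonged to the lipid lists described next. The others were TNFSF13B, which encodes the B cell survival factor BAFF (log2 fold change −0.85 ± 0.104, SE), and NFE2, an erythroid and megakaryocytic transcription factor (−0.82 ± 0.091, SE). All of these genes passed whichever library was left out.

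**Figure D1:**
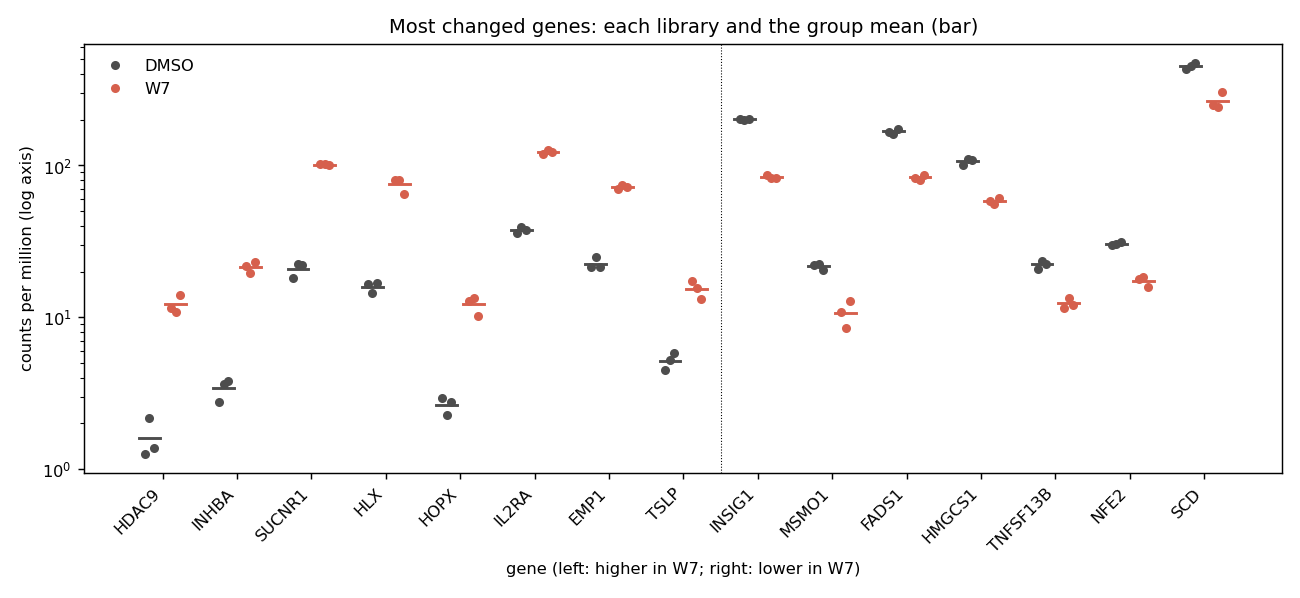
Scaled read counts (CPM, log axis) of the 8 largest named rises and 7 of the largest named falls, with a point for each of 3 DMSO and 3 W7 libraries and a bar at the group mean. HDAC9 lies near 1.603 CPM with DMSO and 12.19 CPM with W7, INSIG1 at 202.6 and 83.7 CPM, and the groups do not overlap for any gene shown.

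All 20 tested genes of cholesterol synthesis had a negative log2 fold change, with a median of −0.51. Of these, 11 fell by the test over all genes and 17 when adjusted over the list alone, and 0 rose. MSMO1, a sterol C4 demethylation enzyme, fell from 21.7 ± 1.1 to 10.7 ± 2.15 CPM (SD, n = 3 per group), and HMGCS1, the HMG-CoA synthase at the entry of the pathway, from 106.5 ± 5.27 to 58.04 ± 2.69 CPM (SD, n = 3 per group). DHCR7, the last reductase of the pathway, changed by −0.76 ± 0.069 (log2, SE), the squalene synthase gene FDFT1 by −0.61 ± 0.064 and the squalene epoxidase gene SQLE by −0.58 ± 0.065. The list passed camera with its preset correlation (adjusted p = 5.8e-16) and not with an estimated correlation (adjusted p = 0.0627). Fry, which asks whether the list's own genes moved on balance one way, gave an adjusted p of 0.000674. No list passed camera with an estimated correlation, against 8 with the preset one.

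Of 14 tested genes of sterol uptake and SREBP2 feedback, 5 fell and 1 rose, with a median log2 fold change of −0.24. Adjusted over the list alone, 8 fell and 1 rose. INSIG1 (chromosome 7, 155297776 to 155310235) led the list. SREBF2, which encodes the transcription factor SREBP2, fell from 161.3 ± 5.2 to 101.5 ± 4.8 CPM (SD, n = 3 per group). The list had a camera adjusted p of 0.000131, and 0.208 with an estimated correlation.

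Fatty acid synthesis genes fell in 5 of 13 cases and rose in 0, with a median log2 fold change of −0.22, and 7 fell when adjusted over the list alone. The desaturase genes led the list. FADS1 fell from 167.7 ± 6.7 to 83.35 ± 3.2 CPM, FADS2 from 342.4 ± 11.8 to 203.6 ± 9.66 CPM and SCD, the stearoyl-CoA desaturase gene, from 452.2 ± 18.6 to 266.6 ± 34.4 CPM (SD, n = 3 per group). SREBF1, which encodes SREBP1, changed by −0.48 ± 0.071 (log2, SE), and by −0.31 with the length and GC trends removed in a single pass, where it still passed. The list passed camera (adjusted p = 1.04e-05; adjusted p = 0.251 with an estimated correlation). FADS1 and FADS2 share exon sequence on opposite strands, as do SREBF1 and RAI1, and FADS2 overlaps FEN1 on the same strand, so their values are uncertain.

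**Figure D2:**
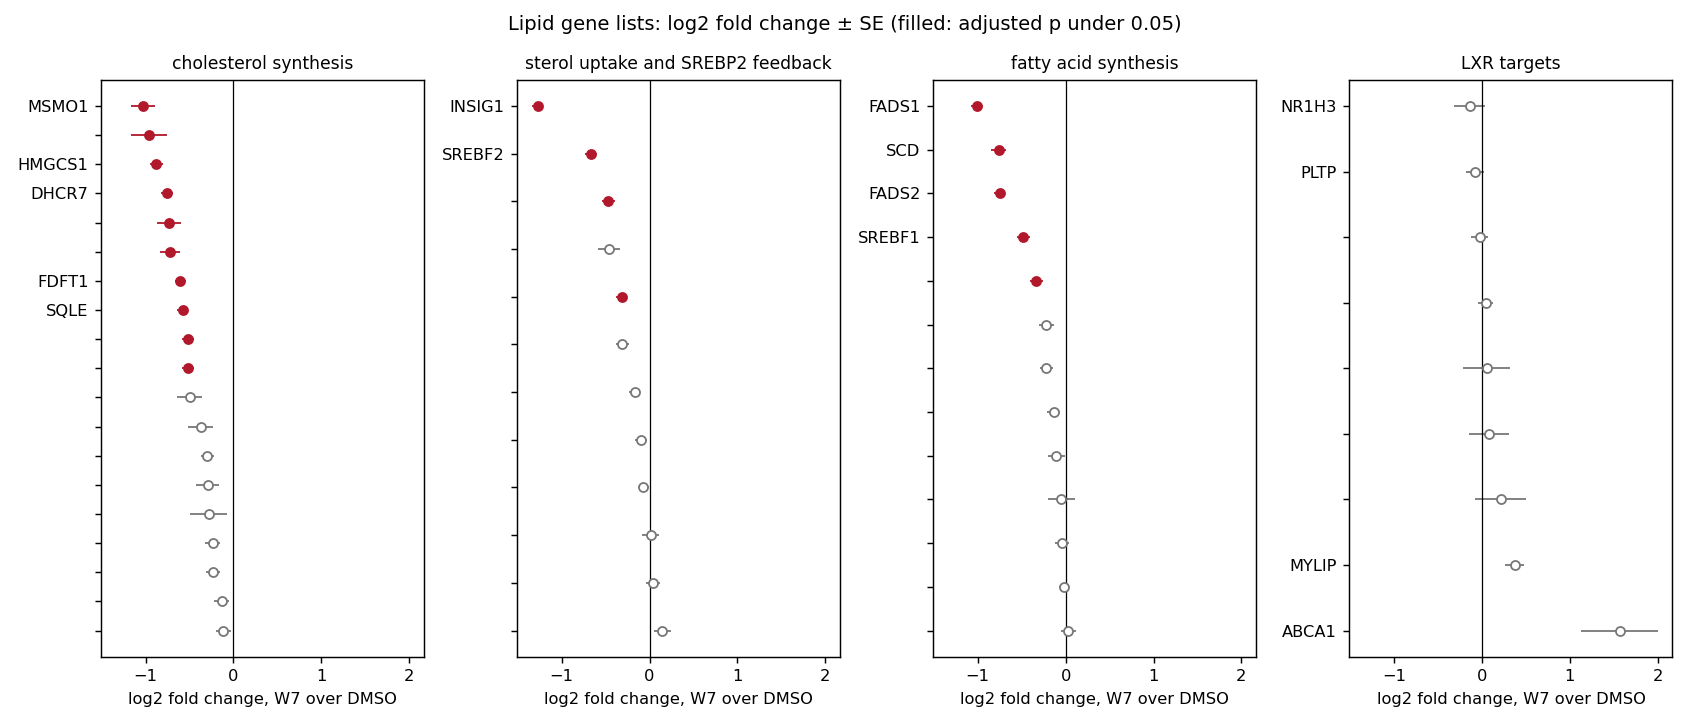
Log2 fold change of W7 over DMSO (points) with its standard error (lines) for the genes shown of 4 lipid lists, filled where the adjusted p was under 0.05 and labelled where the gene is named in the text. All 19 cholesterol synthesis genes shown lie below 0, INSIG1 lies lowest at −1.28, and ABCA1 lies highest at 1.57 without passing.

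Among LXR targets, genes switched on by oxysterol-bound nuclear receptors, 0 of 9 passed over all genes and 2 rose when adjusted over the list alone. These were ABCA1, the cholesterol efflux transporter, at 0.373 ± 0.213 CPM with DMSO and 1.137 ± 0.226 CPM with W7 (SD, n = 3 per group; edgeR adjusted p = 0.0997 over all genes), and MYLIP, a ubiquitin ligase gene, with a log2 fold change of 0.38 ± 0.105 (SE). NR1H3 had a log2 fold change of −0.14 ± 0.175 and PLTP of −0.08 ± 0.103 (SE), and both share exon sequence with a gene on the opposite strand. Their signs were not stable: NR1H3 was at 0.016 without W7 replicate 3, and PLTP at 0.074 with the length and GC trends removed in a single pass. The median of the list was 0.06 and its camera adjusted p was 0.245. The median was −0.04 without DMSO replicate 2 and 0.103 without DMSO replicate 1, so its sign rests on a single library.

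Among the OSBP family and its partners at contact sites, 2 of 22 genes rose and 0 fell, over all genes and when adjusted over the list alone. COL4A3BP, the ceramide transfer protein gene, rose 1.43-fold, from 65.97 ± 6.87 to 94.58 ± 6.91 CPM (SD, n = 3 per group), and OSBPL3 rose 1.27-fold. COL4A3BP shares exon sequence with POLK on the opposite strand, and did not pass without DMSO replicate 1 (adjusted p = 0.0994), DMSO replicate 2 (0.0826) or W7 replicate 1 (0.0734), with edgeR. OSBPL3 did not pass without any one of the DMSO replicates or without W7 replicate 1 (adjusted p from 0.142 to 0.249, edgeR). OSBPL8 (log2 fold change 0.3 ± 0.115, SE) and OSBPL7 (−0.22 ± 0.098, SE) did not pass. With the length and GC trends removed in a single pass their log2 fold changes were 0.161 and −0.092. The list had a median of 0.07 and a camera adjusted p of 0.124, and its median was 0.042 without DMSO replicate 1 and 0.034 with those trends removed in a single pass. Intracellular sterol transport (0 of 12 passed, camera adjusted p = 0.814) and sphingolipid synthesis (0 of 17, camera adjusted p = 0.673) did not pass limma's camera either.

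Immediate early genes, which respond to signals without new protein synthesis, rose in 5 of 17 cases and fell in 1, with a median log2 fold change of 0.36. Adjusted over the list alone, 9 rose and 1 fell. JUN rose from 8.748 ± 0.601 to 20.65 ± 3.87 CPM (SD, n = 3 per group), ATF3 1.61-fold and FOSL1 1.42-fold. MYC fell from 688.6 ± 25.4 to 541.1 ± 17.5 CPM (SD, n = 3 per group). ATF3, FOSL1 and MYC each missed the threshold when one of several single libraries was left out, with adjusted p (edgeR) up to 0.0864 for ATF3, 0.081 for FOSL1 and 0.0808 for MYC. The list passed camera with an adjusted p of 6.8e-07, and 0.208 with an estimated correlation.

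Golgi genes had a median log2 fold change of 0.14, and of 0.091 without W7 replicate 1. Of 20 tested, 2 rose over all genes, ST3GAL1, a sialyltransferase gene, from 71.73 ± 3.3 to 126.1 ± 16.1 CPM, and STX3, a syntaxin gene, from 33.11 ± 1.67 to 44.45 ± 0.726 CPM (SD, n = 3 per group). Adjusted over the list alone, 7 rose and 1 was lower. STX3 did not pass without any one of the DMSO replicates or without W7 replicate 1 (adjusted p from 0.0666 to 0.124, edgeR). UAP1L1 had a log2 fold change of −0.34 ± 0.103 and ACBD3 of 0.29 ± 0.087 (SE), and neither passed over all genes. The camera adjusted p of the list was 0.00968, and 0.208 with an estimated correlation.

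Another 3 lists passed camera although 0 of their members passed singly, over all genes. Mitosis genes had a median log2 fold change of 0.12 (camera adjusted p = 0.0233; adjusted p = 0.208 with an estimated correlation; 0.0555 without DMSO replicate 3), with CENPE at 0.27 ± 0.088, CCNB2 at 0.18 ± 0.059, BUB1 at 0.17 ± 0.059 and HMMR at 0.16 ± 0.06 (SE). Cytosolic heat shock genes had a median of 0.1 (camera adjusted p = 0.0311; adjusted p = 0.477 with an estimated correlation), with HSPB1 at 0.25 ± 0.094, HSP90AA1 at 0.2 ± 0.072, DNAJA1 at 0.17 ± 0.062 and CHORDC1 at 0.16 ± 0.068 (SE). HSPB1 passed without W7 replicate 3 (log2 fold change 0.334, edgeR adjusted p = 0.000895) and with the length and GC trends removed in a single pass (0.452, 0.000129) or in 5 rounds (0.428, 0.000196), and was at 0.142 without W7 replicate 2. CHORDC1 was at 0.048, CENPE at 0.103 and HMMR at 0.084 after the single pass. The heat shock list missed the threshold without DMSO replicate 1 (0.0686), DMSO replicate 3 (0.0694) or W7 replicate 2 (0.139, with a median of 0.067). With the length and GC trends removed in 5 rounds, the medians were 0.064 for mitosis and 0.06 for heat shock. Myeloid markers had a median of −0.23 over 8 genes (camera adjusted p = 0.0262; adjusted p = 0.468 with an estimated correlation). The myeloid regulators CEBPA and SPI1 had log2 fold changes of −0.49 ± 0.125 and −0.34 ± 0.095 (SE), and both were lower when adjusted over the list alone and over all genes without W7 replicate 3 (edgeR adjusted p = 0.0137 and 0.0161) but not after the single pass (−0.259 and −0.128, with 0.171 and 0.202), while MPO (−0.52 ± 0.256, SE) and CST7 (−0.22 ± 0.171, SE) were not. The myeloid list missed the threshold without DMSO replicate 2 (0.0541) or W7 replicate 3 (0.139), and its median was −0.13 without W7 replicate 3 and −0.131 with the length and GC trends removed in a single pass.

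The other lists did not pass camera, although single members did. BMF, a pro-apoptotic member of the BCL2 family, rose 2.33-fold from 5.94 ± 0.771 CPM (SD, n = 3). In that family 2 of 13 genes rose (adjusted p = 0.348, camera of limma). BTG2, an antiproliferative p53 target, rose 1.8-fold as the 1 gene of 15 p53 targets that passed (0.173). SPRY2, an inhibitor of growth factor signalling, rose 1.58-fold, and 3 of 19 genes of BCR-ABL and STAT5 output rose (0.0928). TNFAIP3, an inhibitor of NF-kB, rose 1.75-fold, with 2 of 13 NF-kB and inflammatory genes higher and 1 lower (0.833). IFIH1, an RNA sensor, rose 1.35-fold as the 1 of 14 interferon genes that passed (0.977). SLC2A3, a glucose transporter gene, rose 1.5-fold as the 1 of 17 hypoxia and glycolysis genes that passed (0.977). CCNE2, a cyclin gene that overlaps INTS8 on the opposite strand, rose 1.26-fold as the 1 of 20 DNA replication genes that passed (0.846). IFIH1 did not pass without any one of 4 libraries (adjusted p up to 0.195, edgeR) or after thinning (0.0831), nor CCNE2 without any one of 5 (up to 0.239) or with upper-quartile factors (0.0578). ATF3 was the 1 of 21 ATF4 targets that passed (0.977).

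With edgeR for single genes and limma's camera for lists, no member passed over all genes in the lists of endoplasmic reticulum chaperones (20 genes, camera adjusted p = 0.559), NRF2 targets (18 genes, 0.124), lysosome and autophagy (24 genes, 0.963), ribosome biogenesis (20 genes, 0.251), lymphoid markers (7 genes, 0.88), mitochondrially encoded mRNA (13 genes, 0.124) and replication-dependent histones (12 genes, 0.0928). Without W7 replicate 3 the mitochondrial list passed limma's camera (median log2 fold change 0.25, adjusted p = 0.000173), as it did without DMSO replicate 2 (0.00765). Without W7 replicate 1 its median was 0.031 (0.629), against 0.123 with all libraries and 0.048 with the length and GC trends removed in 5 rounds. These calls used the preset correlation of 0.01. The correlation estimated between its genes was 0.898, and with it the camera adjusted p was 0.829 with all libraries. The histone list had a median of 0.385 with all libraries and 0.436 after thinning (camera adjusted p = 0.0453). It was 0.62 without W7 replicate 1 (1.86e-05) and 0.039 without W7 replicate 3 (0.946), so the histone list rests on single libraries as well. The correlation estimated between its genes was 0.783, and with it the camera adjusted p was 0.761 with all libraries. The median and the mean or test differed in sign for the lysosome, BCL2, NF-kB and interferon lists. Erythroid, megakaryocyte and adherent cell markers had only 2, 3 and 3 genes above the filter and were not tested as lists. NFE2 was the 1 megakaryocyte marker that fell.

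Fold changes followed GC content across genes, beside all of these groups. The Spearman correlation between the log2 fold change and the GC content of the transcript was −0.486 across 12927 genes, which are not independent replicates, and −0.337 without W7 replicate 3. The 4310 genes of lowest GC content had a median log2 fold change of 0.09, with 73 higher and 19 lower, and the 4309 of highest GC content −0.12, with 46 higher and 63 lower. Median GC content was 45% in the genes that rose, 56.7% in those that fell and 47.5% in all genes tested. It was 48.3% in the cholesterol synthesis list, 51.1% in the sterol uptake list, 48.9% in the fatty acid list, 55.3% in the immediate early list, 47.8% in the Golgi list, 44.4% in the mitosis list, 45.2% in the heat shock list and 55.6% in the myeloid list. Each library's trend with GC content, against the mean of all libraries, was positive with DMSO (0.504, 0.224 and 0.222) and negative with W7 (−0.174, −0.066 and −0.442; exact two-sided permutation p = 0.1, the smallest possible). With the trends on length and GC content removed in a single pass, 473 genes passed, of which 246 were among the 282, and with 5 rounds 443, of which 234 were.

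**Figure D3:**
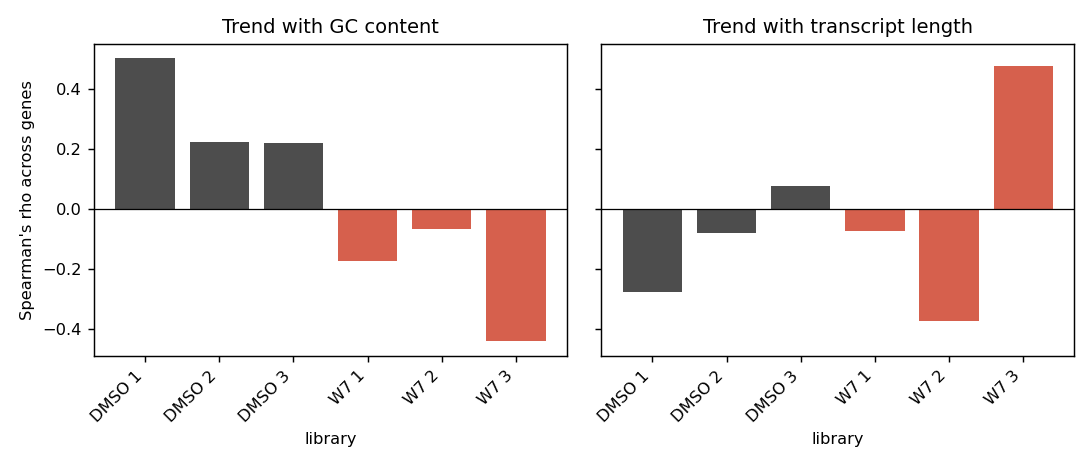
Spearman's rho across genes between a library's log2 CPM, relative to the mean of all 6 libraries, and the GC content (left) or length (right) of the transcript, with a bar per library. The GC trend is positive in the 3 DMSO libraries and negative in the 3 W7 libraries, and W7 replicate 3 has the highest trend with length (0.477).

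W7 replicate 3 stood apart from the other libraries. Its counts differed from those of the other W7 libraries with a chi-square per degree of freedom of 8.106 and 13.19, where the other pairs within a group ran from 1.894 to 2.935, so no library was a copy of another. Spearman correlations between libraries were 0.9905 to 0.9972 within groups and 0.9875 to 0.9948 between groups, and the first principal component held 38.73% of the variance. Mitochondrially encoded genes took 2.53 ± 0.219% of the counts with DMSO and 2.8 ± 0.387% with W7 (SD, n = 3 per group; exact two-sided permutation p = 0.3, Benjamini-Hochberg 0.36 over 6 measures). Their share was 3.05% and 2.99% in W7 replicates 1 and 2 but 2.35% in W7 replicate 3, with 2.33% to 2.76% in the DMSO libraries. The design allows no p below 0.1, which the TMM factor reached (1.01 ± 0.00579 with DMSO, 0.988 ± 0.0113 with W7; SD, n = 3 per group; exact two-sided permutation p = 0.1, Benjamini-Hochberg 0.36).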

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

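Results with length and GC correction or thinning were chosen after the data had been examined. No named gene that passed reversed under any alternative run: of 38 named genes that passed, 29 passed in every alternative (glmTreat, counted only in total, aside), and 9 missed the threshold in at least 1, each of them when a library was left out and 2 of them with all libraries kept as well (CCNE2 with upper-quartile factors, IFIH1 after thinning). Of the 21 others, 10 passed in at least 1 alternative.

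The count of 282 genes (178 higher, 104 lower) became 613 (372 and 241, with 16 lower by at least 1 on the log2 scale) with no low-count filter, 473 (299 and 174) with the length and GC correction, 443 (290 higher) with that correction in 5 rounds, and 29 (27 and 2, of which 24 higher and 2 lower by at least 1 on the log2 scale) with glmTreat, which asks for a larger change by construction. RLE (275), upper-quartile factors (277, of which 57% higher), a CPM filter (284), thinning (250), DESeq2 (292) and limma-voom (273) stayed within 1.5 times, and the median log2 fold change of all genes moved by at most 0.02. Leaving out 1 library gave 112 to 1217 genes, 77 to 680 higher and 33 to 537 lower, with 3 to 13 lower by at least 1 on the log2 scale. At an equal spread between libraries, fewer libraries leave fewer genes past the threshold. The rise to 1217 without W7 replicate 3 goes with the larger spread that this library brings, and its cause was not tested beyond that.

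With the replicate block 471 genes passed (276 higher, 195 lower). Replicate numbers were not taken to pair the samples: same-numbered libraries' deviations from their group means correlated at 0.12, −0.038 and 0.17, and W7 replicate 2 correlated best with DMSO replicate 1 (0.17). The block changed no call among the 8 lists that passed, and the mitochondrial (0.0482) and histone (0.044) lists passed camera with it. With an estimated correlation and no block, the camera adjusted p was 0.829 for the mitochondrial list and 0.761 for the histone list.

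Of 8 lists, 0 passed camera with an estimated correlation. Adjusted p was then 0.0627 for cholesterol synthesis, 0.251 for fatty acid synthesis, 0.477 for heat shock and 0.468 for myeloid markers. It was 0.208 for each of sterol uptake, immediate early, Golgi and mitosis genes. The correlations estimated for the Golgi (0.007) and mitosis (−0.016) lists lay below the preset 0.01, so a higher correlation cannot account for their loss. Those of the others lay above 0.01, from 0.043 (cholesterol synthesis) to 0.226 (fatty acid synthesis). Whether that cost the calls was not tested. Fry, which compares a list with no other genes, passed 19 lists for mixed directions. Directional fry gave an adjusted p of 0.000674 for cholesterol synthesis and sterol uptake. It was 0.0111 for fatty acid synthesis, 0.00873 for mitosis, 0.0162 for Golgi and for immediate early genes, and 0.0334 for BCR-ABL and STAT5 output. Adjusted p for heat shock was 0.0542 with no low-count filter, 0.0888 with directional fry and 0.0153 to 0.139 with 1 library left out. For myeloid markers it was 0.065 after thinning, 0.13 with directional fry and 0.00987 to 0.139 with 1 library left out, and for mitosis 0.0109 to 0.0555. The cause of these losses was not tested. Cholesterol synthesis kept its call in all 14 camera alternatives with the preset correlation (highest adjusted p 1.56e-12), as did sterol uptake (0.00121), fatty acid synthesis (0.000583), immediate early (9.54e-05) and Golgi genes (0.0262). With 9354168 to 12107735 counts a library, genes such as ABCA1 at about 1 CPM rest on few reads, which limits what can pass.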

Other observations

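The tests on counting noise and on trends fitted in rounds were chosen after results had been seen, as were the corrections themselves. Several genes outside the naming rule changed as well. They were chosen after their values were seen, with no test of enrichment. Among the class IIa histone deacetylases, 3 of 4 rose: HDAC9, HDAC5 from 17.12 ± 1.35 to 48.88 ± 2.6 CPM and HDAC7 from 58.31 ± 3 to 80.91 ± 5.41 CPM (SD, n = 3 per group), while HDAC4 had a log2 fold change of −0.05 ± 0.113 (SE). Of the 7 other zinc-dependent deacetylases tested, 0 passed in edgeR's test, and these counts were the same with RLE and upper-quartile factors. Of 3 tested MEF2 factors, partners of class IIa deacetylases, 2 rose, MEF2C 1.31-fold and MEF2D 1.41-fold, and MEF2A did not pass (edgeR adjusted p = 0.0773). With the length and GC trends removed, in a single pass (MEF2A adjusted p = 0.022) or in 5 rounds, and without W7 replicate 3, 3 of 3 passed as higher. The nuclear receptor genes NR4A1 and NR4A2 rose 2.08-fold and 2.29-fold at under 5 CPM. RNF145, which encodes a ubiquitin ligase of sterol metabolism, rose 1.75-fold and IDH1, an enzyme that yields NADPH, changed by −0.48 ± 0.067 (log2, SE).

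Some genes picked because they had passed, so that they stand for no group, encode surface proteins. Of 13 such genes picked, 7 rose and 6 fell. CD69, an early activation marker, rose from 95.19 ± 2.97 to 186.4 ± 13.8 CPM and CD44 from 173.1 ± 5.98 to 250.7 ± 22 CPM (SD, n = 3 per group). CD180 rose 4.09-fold from a low level, 1.85 ± 0.259 to 7.716 ± 2.12 CPM, while CD86 fell from 176.5 ± 6.59 to 121.9 ± 4.73 CPM (SD, n = 3 per group). The growth factor genes HBEGF and FGF2 rose 1.75-fold and 2.27-fold.

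The fall of cholesterol synthesis genes (list median −0.51) was weighed against 3 technical explanations. Removing the trends with length and GC content left the median at −0.457 in a single pass and at −0.433 after 5 rounds, which argues against those trends as the whole cause. It was −0.44 without W7 replicate 3, which argues against that library alone. Thinning to equal library totals left it at −0.509. Fold changes were already scaled to the totals, so thinning could hardly move the median and does not decide on unequal totals. The list was fixed before the data were examined, but the corrections and thinning were chosen afterwards. A response to W7 itself stays a hypothesis, tested on these libraries alone, and no mechanism was tested.

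The small rises of the Golgi and mitosis lists (medians 0.14 and 0.12) may depend on the GC trend that separates the groups. After the single-pass correction the medians were 0.154 and 0.084, both still past the threshold and above the bound set for a trend as the cause, and without W7 replicate 3 they were 0.169 and 0.103. After 5 rounds the Golgi median was 0.12, again above its bound. The mitosis median of 0.064 was also above its bound, but only just. With a margin chosen after the values were seen, a trend and a change in mitosis genes cannot be told apart. An effect of W7 on these genes stays open for both lists, and because the GC trend has one sign in the DMSO libraries and the other in the W7 libraries, its own origin was not separable from treatment.

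The distance of W7 replicate 3 from the other libraries was weighed against depth, length or GC trends, and a different response to W7. The tests set first, on the ratio of its mean distance within its group to that of the next library, decide nothing. The ratio was 1.105 at the start, 1.086 after thinning and 1.077 after the correction, the last 2 under a bound of 1.1, but a prior count of 0.5 alone gave 1.098, and the next library's distance itself includes W7 replicate 3. A chi-square against counting noise was chosen after the first ratios were seen. Its lowest value per degree of freedom for W7 replicate 3 was 8.106 at the start and 7.4 after thinning (highest of the other pairs 2.599). The expected counts were already scaled to the library totals, so thinning could hardly move this value and does not decide on depth. It was 4.33 after the correction (2.296) and 4.34 after 5 rounds (2.297). This argues against length and GC trends as the whole cause, though they may account for a part. The cholesterol synthesis response of W7 replicate 3 was 1.08 times the mean of the other W7 libraries, which argues against a weaker or stronger response of those genes. The response of other genes to W7, and what else set this library apart, were not tested.

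Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many as 282 genes, the real one, and the highest of the others gave 0 in edgeR's test (1116 at an unadjusted p under 0.05, against 2221, which was 1385 without DMSO replicate 1). For lists 1 split, the real one, gave as many as 8. Every other split gave from 1 to 5 lists although it passed 0 genes, so lists passed under wrong groupings as well. Splits of 6 libraries are too few for a share under 0.05. After removal of the length and GC trends, chosen after the data had been examined, LXR targets passed limma's camera as higher (medians 0.128 and 0.135, adjusted p = 0.0165 and 0.0209 in the 2 versions; up to 0.72 over all alternatives), although their median was −0.04 without DMSO replicate 2. So did BCL2 family genes (medians 0.065 and 0.056, from −0.001; adjusted p = 0.0122 and 0.0209; up to 0.72) and BCR-ABL and STAT5 output (0.00626 and 0.00451; up to 0.468). NRF2 targets passed as lower in 5 rounds (median log2 fold change −0.054, camera adjusted p = 0.0328) and not in a single pass (−0.031, 0.103), with an adjusted p of 0.477 with an estimated correlation.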
